A study of Homo sapiens with 4 samples.

How the data were processed

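RNA of the human gastric carcinoma line MKN28 was measured on 4 two-colour Agilent arrays of one slide, scanned in one session. Per the labels, cells were transfected with a pool of siRNAs against SP1 or with control siRNA, RNA was taken at 72 h, and 100 ng of each RNA was amplified and labelled with Cy3 or Cy5. The deposited scanner files hold, per the file headers, the output of Agilent Feature Extraction 10.1.1.1: median spot and local background intensity of each colour, processed intensity (background-subtracted and dye-normalized) and a log10 ratio of red over green. The grid was built on hg18, per the file headers. The deposited series table holds log10 ratios that matched the scanner's log10 ratio on every spot to within 0.005, with the sign turned on arrays 1 and 2. Its columns therefore run as RNA labelled SP1 siRNA over RNA labelled control siRNA, with medians of 0, -0.0126, 0 and -0.0103, and no scale, centring or direction stays unknown.

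Each array held 45015 spots, of which 1639 were controls. Signals were corrected with normexp (offset 50) in limma 3.58.1 (R 4.3.3). The design fixed before the data were examined named mean spot signals. The files read here give medians, which were used instead. Log2 ratios were normalized within each array by loess, with weight 0 for control spots and for spots marked as non-uniform or population outliers, and these spots were then left out. Spots of a probe were averaged, giving 41000 probes. The files give accessions but no gene names. Of the probes, 23958 (58.4%) were named through the RefSeq table of assembly GRCh38.p14 after accession versions were removed, giving 16557 symbols. That build differs from the grid's, so no coordinates are given. Probes without a match kept their accession. The brightest tested probe stood for a gene.

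All 4 arrays form one group by their channel labels, each setting RNA labelled SP1 siRNA against RNA labelled control siRNA. Every ratio was turned to that direction, and the arrays of a replicate were averaged. The descriptions number arrays 1 and 2 as replicate 1 and arrays 3 and 4 as replicate 2. The RNA labelled SP1 siRNA was in Cy3 in replicate 1 and in Cy5 in replicate 2, so dye and replicate number coincide. A probe was tested where one RNA was well above background on all arrays. The mean of 2 replicate values was tested against 0 with limma's lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05. This is called the comparison as labelled below.

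A comparison by title was added after the data were seen. The submitters' titles call one array of each replicate Control and the other SP1. The log2 ratio of RNA labelled control siRNA over RNA labelled SP1 siRNA on the Control array was subtracted from that on the SP1 array of the same replicate and dye. The 2 differences were tested as above, over probes where the RNA labelled control siRNA was well above background on both arrays of one title. The labels conflict on replicate 2: the descriptions call it a biological replicate, whereas the titles of arrays 3 and 4 and the series' design text call it a dye swap. If it holds the same RNA as replicate 1, every SD with n = 2 and every p-value measures only the spread between arrays.

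For bounds, per-channel levels were taken after loess and Aquantile scaling. A gene not well above background in one RNA on any array has the lowest signal among probes well above background, or its own where higher, as its level there, and is given as at least that fold. With 33 gene lists fixed before the data were examined, limma's camera was run at a preset correlation of 0.01, on lists with 5 or more tested members and without SP1, and again with a correlation estimated from the residuals, which had 1 degree of freedom. The camera test then also has 1 degree of freedom, so a call lost there need not reflect correlation between genes. The fry test was also run. It asks whether a list's genes differ from no change, whereas camera asks whether they differ from the other genes. Named genes were, by a rule fixed before the data were examined, SP1, the 12 largest changes in each direction past the threshold with one sign throughout, up to 4 members of each list that passed or had 2 or more called members, every called SP or KLF factor, SP3 and SP4. Other names are said to be chosen after their values were seen or are members of a list whose count is given. Some genes that the rule takes are not reported here. XIST and Y-linked genes were left out of all printed results.

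Both comparisons were tested on simulated data. As labelled, over 25696 genes, 0% of 1.2-fold changes and 100% of 1.5-fold changes were recovered, and 0% of unchanged genes were called. By title, over 23767 genes, 52% of 1.2-fold and 100% of 1.5-fold changes were recovered, and 0.0510% of unchanged genes were called. A shifted mitosis list was recovered in both, with 3 other lists called as labelled and 0 by title. A dye bias per gene was added with a spread set by hand, not taken from the arrays. It widens the spread between replicates as labelled and cancels by title. The rates as labelled thus rest partly on that setting. For both comparisons, the noise of each array was drawn independently, for all genes from a single pool of differences between the real arrays. These rates therefore do not cover spread that differs between genes, or differences between samples in culture or labelling. The number of arrays limits the precision. Alternatives covered the background correction, scaling within and between arrays, the deposited table, the filter on dim probes, the probe rule, marked spots, the variance model, the treatment of replicates and leaving out each array and replicate. Figures were drawn with matplotlib 3.10.9.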

Results

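Gene expression was profiled in MKN28, a cell line described as intestinal-type gastric carcinoma, after transfection with siRNA against SP1, a zinc-finger transcription factor that binds GC-rich promoter sequences, or with control siRNA. The question addressed by the design is which transcripts differ at 72 h. Each of 4 arrays held one RNA labelled SP1 siRNA and one labelled control siRNA, in 2 replicates of 2 arrays with the dyes exchanged between replicates. Median spot intensity was 135 to 215 in green and 252 to 396.5 in red, over backgrounds of 39 to 42 and 54. Between 79.8% and 83.9% of spots were well above background in the RNA labelled SP1 siRNA and between 72.4% and 77.1% in the RNA labelled control siRNA. No spot was saturated.

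SP1 itself was examined first, in every array. Its brighter probe (A_23_P366312) gave log2 ratios of RNA labelled SP1 siRNA over RNA labelled control siRNA of -1.13, 0.99, -1.39 and 0.68 on arrays 1 to 4. The other SP1 probe (A_23_P53397) gave -0.85, 0.52, -0.84 and 0.56. SP1 was therefore lower in the RNA labelled SP1 siRNA on the arrays titled Control (1 and 3) and higher in it on those titled SP1 (2 and 4), against the channel labels. The mean was -0.21 ± 0.21 (SD, n = 2 replicates; limma adjusted p = 0.0911), but -0.56 with Agilent's processed signals (adjusted p = 0.00497) and -0.56 with the deposited table (adjusted p = 0.00623), where it passed. Each replicate value averaged an array with SP1 lower and an array with SP1 higher. This SD and these p-values therefore leave out the opposition between the arrays of a replicate. Fits to the 4 arrays, which keep it in the spread, gave limma adjusted p of 0.660 (arrays as independent), 0.713 (dye term) and 0.748 (replicate as random block). The mean became 0.32 without array 1 and -0.74 without array 2. Because the target contradicts a label, RNAs are named below only as labelled, and no direction is read as an effect of the siRNA.

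The movement of SP1 lay in the RNA labelled control siRNA. Between arrays titled Control and those titled SP1, its level in that RNA fell by 2.14 ± 0.04 on the log2 scale (SD, n = 2 replicates) with the brighter probe, a 4.40-fold difference, and by 1.40 ± 0.10 with the other. In the RNA labelled SP1 siRNA the brighter probe differed by -0.04 ± 0.01. Over 32802 probes the 2 RNAs behaved likewise: between arrays of one dye, the SD of the log2 difference was 0.0950 and 0.0873 for the RNA labelled SP1 siRNA, and 0.262 and 0.243 for the RNA labelled control siRNA. Within each array the 2 RNAs differed with an SD of 1.12 to 1.16.

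**Figure D1:**
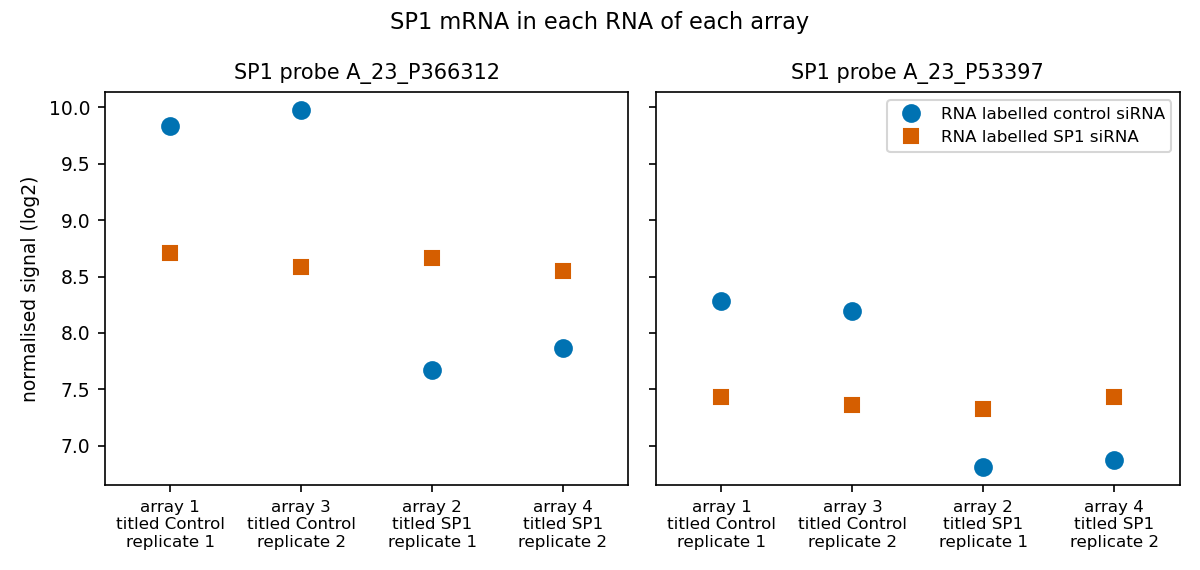
SP1 mRNA as normalised log2 signal (vertical axis) in each RNA of each array (horizontal axis), for the 2 SP1 probes; each point is 1 array. The RNA labelled control siRNA lies above the RNA labelled SP1 siRNA on the arrays titled Control and below it on those titled SP1, with means of 9.91 and 7.77 for probe A_23_P366312.

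As labelled, AHSG, a plasma glycoprotein of the liver, was 511-fold higher in the RNA labelled SP1 siRNA, BNIP3, a mitochondrial protein induced by hypoxia, 458-fold (log2 8.84 ± 0.18, SD, n = 2), RHOXF2, a homeobox factor of the germ line, 324-fold and IGFBP1, an insulin-like growth factor binding protein, 292-fold. ALB (220-fold), APOH (188-fold), A2M (133-fold) and AFP (117-fold) encode plasma proteins. CD44 (198-fold), CXCR4 (144-fold), GNG11 (129-fold) and CPE (110-fold) completed the 12 highest. CPE was well above background on 3 of the 4 arrays in the RNA labelled control siRNA. RHOXF2, GNG11, CXCR4, CD44 and BNIP3 were dim in that RNA, with mean log2 levels of 6.27 to 6.73. The lowest levels well above background there were 5.70 to 6.06, so the size of these folds is uncertain. In the other direction, ADGRF1 and SCEL were not well above background in the RNA labelled SP1 siRNA on any array and were at least 75.5-fold and at least 33.7-fold lower there. COXFA4L3 (46.7-fold), ZBED2 (44.9-fold), XAGE2 (38.2-fold), ANKRD22 (37.2-fold), ZNF750, an epithelial differentiation factor (28.8-fold), ADAM8 (21.9-fold), TMEM125 (21.1-fold), KLK8 (log2 -4.39) and COX7B2 (20.6-fold) were also lower in it. ZBED2, ANKRD22 and ZNF750 were dim in the RNA labelled SP1 siRNA, with mean log2 levels of 6.70 to 6.95. The lowest levels well above background in it were 5.81 to 6.11, so the size of these folds is uncertain too. Adjusted p in limma was at most 1.16e-14 for the genes named here, and all 4 arrays had one sign.

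Of 25696 genes tested as labelled, 18379 (71.5%) differed between the RNAs, 10303 higher and 8076 lower in the RNA labelled SP1 siRNA. With Agilent's processed signals the split turned to 8779 higher and 10867 lower, as the median over genes moved from 0.06 to -0.14. A ratio of at least 2-fold with one sign on every array was found for 5034 genes, or 8423 with Agilent's processed signals, and for 0 genes when coded red over green. Median centring in place of loess left 7827 genes changed.

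Among the fixed lists, genes of epithelial junctions and keratins were lower in the RNA labelled SP1 siRNA (26 of 28 tested lower, 1 higher, 27 called adjusted over the list alone, camera adjusted p = 1.65e-13), including EPCAM (11.8-fold) and GRHL2 (9.79-fold). Mesenchymal genes were higher (23 of 25, 23 adjusted over the list alone, adjusted p = 1.07e-10), with SPARC at 83.1-fold and FBN1 at 55.5-fold. Fibroblast markers were higher too (12 of 13, 12 adjusted over the list alone, adjusted p = 8.23e-07), with LUM at 51.7-fold and COL1A2 at 46.4-fold. With an estimated correlation none of these 3 lists passed (adjusted p = 0.875 for each). Of 17 leukocyte markers, 8 were higher, CD3D by 23.5-fold, and 2 lower, without passing in camera (adjusted p = 0.0920). Of 9 endothelial markers, 5 were higher and 2 lower (adjusted p = 0.668).

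Hypoxia and glycolysis genes (26 of 33 higher, 4 lower, 30 adjusted over the list alone, camera adjusted p = 5.74e-06), antigen presentation genes (17 of 21 higher, 1 lower, 18 adjusted over the list alone, adjusted p = 0.000116) and metallothioneins (9 of 10 higher, 1 lower, 10 adjusted over the list alone, adjusted p = 0.000732) were higher in the RNA labelled SP1 siRNA. HK2, the first enzyme of glycolysis, stood at 79.2-fold and MT1M at 32.7-fold. Mitosis genes (34 of 40 lower, 0 higher, 35 adjusted over the list alone, adjusted p = 6.59e-07) and proteasome genes (23 of 31 lower, 3 higher, 28 adjusted over the list alone, adjusted p = 0.000109) were lower. So were the lists of replication (19 of 40 lower, 9 higher, 28 adjusted over the list alone, adjusted p = 0.0367), interferon response (22 of 40 lower, 13 higher, 35 adjusted over the list alone, adjusted p = 0.0367) and NRF2 target genes (14 of 26 lower, 6 higher, 20 adjusted over the list alone, adjusted p = 0.0485). The number of lists that passed camera moved from 11 to 8 with Agilent's processed signals or the deposited table. It moved to 16 with median centring. With an estimated correlation none of the 11 lists that passed camera did so (adjusted p = 0.875 for each, with 0 lists at an unadjusted p under 0.05). That test had 1 degree of freedom, so it cannot tell whether correlation between genes accounts for the calls. In fry, which tests a list against no change, 3 of the 11 passed, those of epithelial (adjusted p = 0.0213), mesenchymal (0.0255) and hypoxia genes (0.0213), and the other 8 did not (adjusted p = 0.0548 to 0.129). The lists of intestinal epithelium (0.0335), TGF-beta response (0.0255) and leukocyte markers (0.0246) passed in fry alone.

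By title, which sets the RNA labelled control siRNA on arrays titled SP1 against the same on arrays titled Control, SP1 was 4.28-fold lower on the arrays titled SP1 (log2 -2.10 ± 0.03, SD, n = 2 replicate differences; limma adjusted p = 8.29e-06). It ranked 2 by fall among 23767 genes. Only AQP3, a water and glycerol channel, fell further (4.43-fold). The largest rises were SPP1, the secreted phosphoprotein osteopontin (6.33-fold; log2 2.66 ± 0.09), and UBD, a ubiquitin-like modifier (5.47-fold; 2.45 ± 0.18). This comparison was chosen after the data were seen, and it holds only if the titles name the transfected RNA. The labels conflict on whether replicate 2 is a separate culture: the descriptions call it a biological replicate, and the titles call its arrays dye swaps.

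The other genes with the largest rises on arrays titled SP1 were TESC, a calcium-binding protein (3.32-fold), ID2 (3.27-fold), LYNX1 (2.96-fold), CDKN2D, an inhibitor of cyclin-dependent kinases (2.76-fold), SVBP (2.69-fold), IL32, a cytokine (2.67-fold), ID4 (2.63-fold), PAOX, a polyamine oxidase (2.61-fold), ZC2HC1A (2.51-fold) and MEGF9 (2.48-fold). Those with the largest falls were EGR1 (3.18-fold) and JUN (2.55-fold), transcription factors induced early after growth stimulation, DCLK1, a kinase (2.81-fold), NUPR1, a stress-induced nuclear protein (2.75-fold), PSCA (2.47-fold), PDE2A, a cyclic nucleotide phosphodiesterase (2.43-fold), PSMB7, a proteasome subunit (2.40-fold), KRT13, a keratin (2.38-fold), SUSD3 (2.32-fold), TLNRD1 (2.32-fold) and CENPH, a centromere protein (2.31-fold). All had one sign in both replicates and a limma adjusted p of at most 7.56e-05. The log2 level of KRT13 in the RNA labelled control siRNA alone went from 10.67 to 8.78. This fall was larger than that of its ratio (-1.25), so its normalised signal in the other RNA was lower too. For EGR1 the level went from 14.16 to 12.81, a smaller fall than that of its ratio (-1.67). Its normalised signal in the other RNA was thus higher on arrays titled SP1. The cause of these shifts was not tested.

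**Figure D2:**
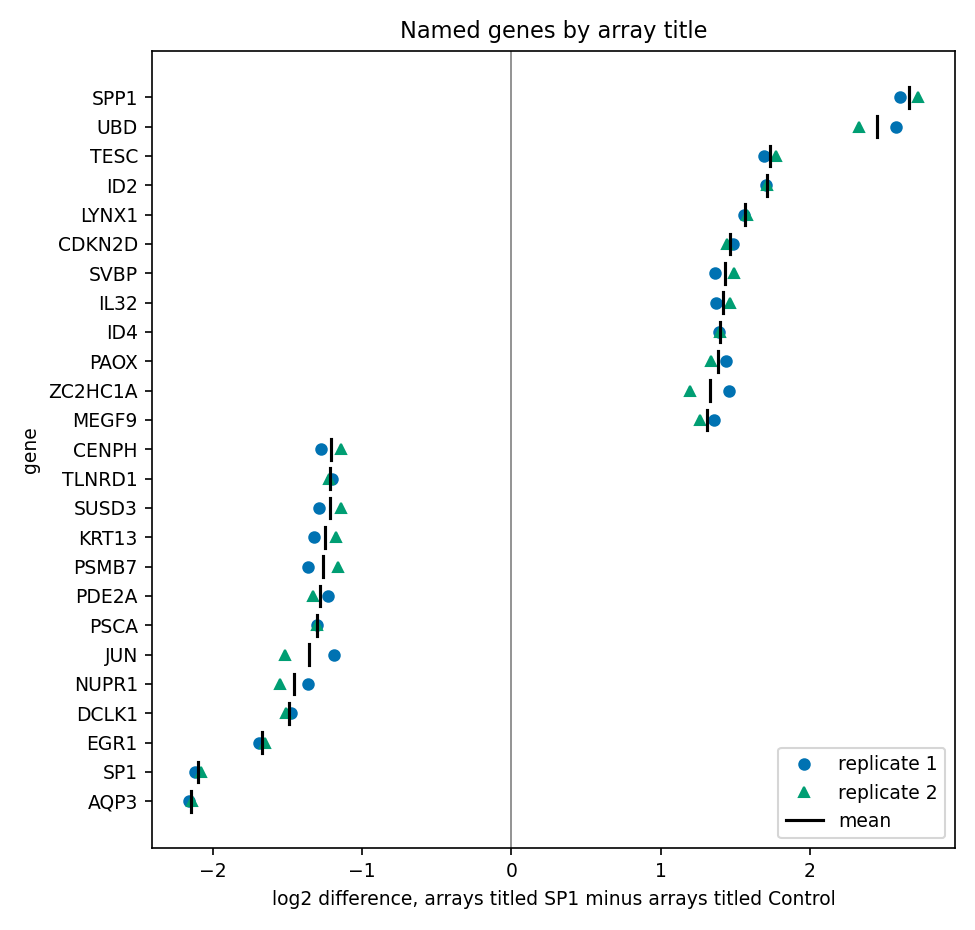
Log2 difference between arrays titled SP1 and arrays titled Control (horizontal axis) for SP1 and the 12 genes with the largest change in each direction (vertical axis), as a value per replicate and their mean. SPP1 stands at 2.60 and 2.73, and SP1 at -2.12 and -2.08.

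By title, 9583 of 23767 genes (40.3%) passed the test, 5064 higher and 4519 lower on arrays titled SP1, and 49.5% of them differed by less than 1.2-fold. A difference of at least 1.5-fold was called for 450 genes higher and 312 lower, and at least 2-fold in both replicates was found for 44 higher and 35 lower. The replicate differences correlated at 0.856 across genes, which are not independent replicates. Without the replicate block, which leaves any difference between the replicates in the spread, 9 genes passed, SPP1, UBD, AQP3, EGR1, TESC, ID2 and LYNX1 among them, and SP1 missed the threshold (adjusted p = 0.0557, the highest of its alternatives, the lowest being 3.54e-06). Agilent's processed signals left 4313 genes called and put 329 at 2-fold in both replicates.

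Genes of cholesterol synthesis were higher on arrays titled SP1: 21 of 25 rose, 1 fell and 3 did not pass (23 called adjusted over the list alone, camera adjusted p = 1.69e-08). The call was lost with an estimated correlation (adjusted p = 0.763). Against no change, which fry tests, adjusted p was 0.0778. LSS, which closes the sterol ring, rose 2.09-fold (log2 1.06 ± 0.09, SD, n = 2), DHCR7, which makes cholesterol from its last precursor, 1.49-fold, and TM7SF2, a sterol reductase, 1.45-fold. In the list of fatty acid synthesis, 2 of 12 rose and 4 fell (8 adjusted over the list alone, adjusted p = 0.185), and SREBF1, a regulator of lipid synthesis, fell 1.59-fold.

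Interferon response genes were higher as well: 23 of 39 rose, 2 fell and 14 did not pass (26 adjusted over the list alone, camera adjusted p = 2.34e-06). This call too was lost with an estimated correlation (adjusted p = 0.763), and adjusted p in fry was 0.0778. IFI6 rose 1.86-fold, IFI44L 1.82-fold and RSAD2, an antiviral enzyme, 1.74-fold. CXCL10, a chemokine, passed too but was not well above background on arrays titled Control, so no fold is given. With Agilent's processed signals neither CXCL10 nor RSAD2 passed (limma adjusted p = 0.0509 and 0.0581), though both differences were larger there. That of RSAD2 was 0.96 on the log2 scale, against 0.80. IFIT2 and OASL fell, and ISG15 stood at -0.01. Antigen presentation genes rose in 9 of 18 cases and fell in 0 (12 adjusted over the list alone, adjusted p = 0.000275), with HLA-F at 1.87-fold, TAP1, a peptide transporter, at 1.72-fold and HLA-DMB at 1.65-fold. The call of this list was lost with an estimated correlation (adjusted p = 0.763), and adjusted p in fry was 0.0617.

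NF-kB and inflammatory genes rose in 17 of 28 cases, fell in 2 and did not pass in 9 (19 adjusted over the list alone, camera adjusted p = 5.99e-05, or 0.763 with an estimated correlation). CCL2, a monocyte chemokine, rose 2.16-fold, BIRC3, an inhibitor of apoptosis, 1.93-fold and PTGS2, which makes prostaglandins, 1.77-fold, while LCN2, an iron-siderophore carrier, fell 1.91-fold. Of 10 genes in the metallothionein list, 9 rose, the zinc exporter SLC30A1 among them, and 0 fell (9 adjusted over the list alone, adjusted p = 0.000779, or 0.763 with an estimated correlation), MT1F by 1.65-fold and MT1X by 1.29-fold. Transcripts of this family are near-identical, so single members are uncertain. Of 40 mitosis genes, 14 rose, NUF2 by 1.29-fold, and 2 fell, ANLN by 1.32-fold and BIRC5, at log2 -0.26 (16 adjusted over the list alone, adjusted p = 0.0476). This call was lost with median centring (adjusted p = 0.138), without the replicate block (0.0967), with offset 0 (0.0893), Agilent's processed signals (0.0657), the mean of probes (0.0646), the deposited table (0.0558) and single channels (0.0533), and its adjusted p ran from 0.0148 to 0.763 over all alternatives. With an estimated correlation none of the 6 lists passed (adjusted p = 0.763 for each, with 0 lists at an unadjusted p under 0.05). The estimate was below the preset 0.01 for antigen presentation, NF-kB and mitosis genes (-0.059, -0.016 and -0.015). It was above 0.01 for interferon, cholesterol and metallothionein genes (0.169, 0.16 and 0.289). That test had 1 degree of freedom, so it cannot tell whether correlation between genes accounts for the calls. The fry test passed 0 lists (adjusted p = 0.0617 to 0.108 for these 6) and had 14 at an unadjusted p under 0.05.

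**Figure D3:**
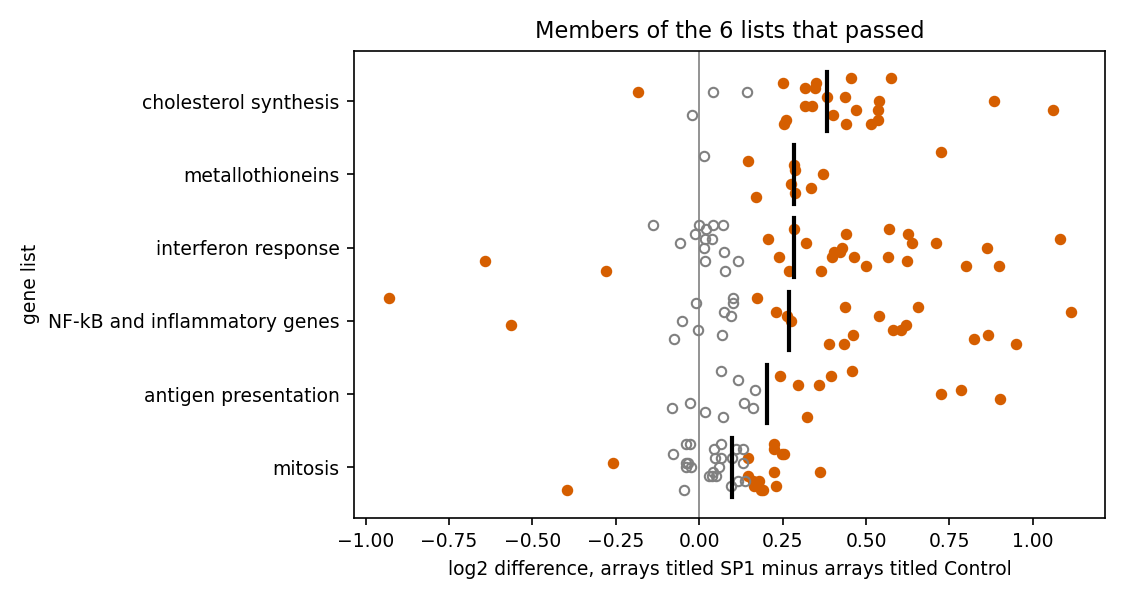
Log2 difference between arrays titled SP1 and arrays titled Control (horizontal axis) for each tested member of the 6 lists that passed camera (vertical axis); filled points passed limma at adjusted p under 0.05, open points did not, and black bars are list medians. Medians run from 0.10 for mitosis to 0.38 for cholesterol synthesis.

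Members of the SP and KLF family of zinc-finger factors went both ways: 5 of 18 rose and 6 fell (12 adjusted over the list alone, camera adjusted p = 0.924). KLF2 fell 2.19-fold, KLF6 1.35-fold, KLF13 1.13-fold and KLF5 1.12-fold. On the log2 scale KLF11 fell by 0.32 and KLF4 fell by 0.27. KLF12 rose 1.64-fold, KLF9 1.52-fold, SP8 1.19-fold and KLF15 1.16-fold. SP3 rose 1.18-fold with probes that disagreed in sign, so it is uncertain, and SP4 was at 0.12 (adjusted p = 0.0954). KLF4, KLF5, KLF13 and SP3 did not pass with Agilent's processed signals. Their log2 differences there (-0.28, -0.17, -0.18 and 0.21) were close to the main values (-0.27, -0.16, -0.18 and 0.24). Of 43 genes with promoters described as SP1-regulated, 16 rose and 10 fell (32 adjusted over the list alone, adjusted p = 0.803). TERT, the catalytic subunit of telomerase, fell 2.09-fold, and THBS1, a matrix glycoprotein, rose 1.75-fold.

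Hypoxia and glycolysis genes (15 of 33 rose, 5 fell, adjusted over the list alone 22, adjusted p = 0.0552) and proteasome genes (6 of 31 fell, 0 rose, adjusted over the list alone 6, adjusted p = 0.0552) missed the threshold. LDHA, lactate dehydrogenase, rose 1.53-fold and PDK1 1.69-fold, whereas DDIT4 fell 1.83-fold. Among TGF-beta response genes, 12 of 24 rose and 4 fell (adjusted over the list alone 18, adjusted p = 0.184). ID1 rose 2.14-fold and ID3 1.64-fold beside ID2. Among NRF2 targets, 4 of 25 rose and 12 fell (adjusted over the list alone 16, adjusted p = 0.283). FTH1, the ferritin heavy chain, rose 2.31-fold and AKR1C3 2.10-fold, and ABCC3, an efflux pump, fell 1.78-fold. Of 28 epithelial junction and keratin genes, 3 rose and 6 fell, CDH1 (E-cadherin) by 1.31-fold and KRT18 by 1.47-fold (adjusted over the list alone 9, adjusted p = 0.889). Of 40 replication genes, 2 rose and 12 fell (adjusted over the list alone 13, adjusted p = 0.316), and CCNE1, cyclin E, rose 1.76-fold. Of fibroblast markers 1 of 10 rose and 3 fell (adjusted p = 0.429), and of leukocyte markers 1 of 17 rose and 3 fell (adjusted p = 0.790). Of 32 lists tested, 26 did not pass.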

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

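All tests here were chosen after the results they bear on had been seen. The prediction for matched random lists was written before its own result, but after the lists it covers had been chosen by camera.

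SP1 had opposite signs on the 2 kinds of array title. As RNA labelled SP1 siRNA over RNA labelled control siRNA, probe A_23_P366312 averaged -1.26 on arrays titled Control and 0.84 on those titled SP1, and probe A_23_P53397 averaged -0.84 and 0.54. This opposition within the channel labels was not tested there; the difference by title was. Of 23375 genes in both comparisons, 815 had one sign on both arrays of one title and the opposite on both of the other. Such genes tend to pass by title, and 729 of them did. Only 36 of the 815 passed with a difference of 1 log2 unit or more. One of 28 quantities checked had an array far from the rest: the ratio of AFP, where the gap was 0.931 of the range over 4 arrays. Chance alone marks about 1 in 20.

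The first pattern is the size of the ratios as labelled together with SP1 moving both ways. A dye effect is argued against, since 0 genes kept a 2-fold ratio of one sign on all 4 arrays when coded red over green. An SP1 knockdown in the RNA labelled SP1 siRNA on every array is argued against by the 2 arrays on which both SP1 probes were higher there, and exchanged channels on the arrays titled SP1 by the correlation of at least 0.978 across genes between the arrays of a replicate. A candidate explanation is that the RNA labelled SP1 siRNA was one common reference RNA that held other cell types: its SD between arrays of one dye was 0.361 of that of the other RNA, and 20 liver markers outside the named genes had a median log2 ratio of 4.15, with 19 higher, FGG by 107-fold and TTR by 46.5-fold. Of these markers, HPX did not pass (log2 -0.08, adjusted p = 0.492), and the sources used here hold no confirmation of the channel labels.

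The second pattern is the difference by title. Noise between arrays that is alike in both RNAs is argued against as the whole cause: over the 9583 genes called, the RNA labelled SP1 siRNA differed between the titles with an SD of at most 0.232 of that of the RNA labelled control siRNA. A difference in the spread of ratios between arrays is argued against as the whole cause, since 89.2% of the genes called stayed called with their sign after scale normalization. SP1 ranked 2 by fall, but the comparison was set up because SP1 had been seen to move between the titles, so this does not decide whether the titles name the siRNA of the RNA labelled control siRNA. Off-target effects of the siRNA pool and chance differences between the samples, in culture or labelling, stay open, as does a technical dye swap as replicate 2.

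The third pattern is the rise of 6 gene lists on arrays titled SP1. A trend with signal or with the ratio to the other RNA is argued against. Medians of 10000 random lists matched on both had middle values of -0.006 to 0.015, so matched genes showed little shift. The list medians lay at or above percentile 98.3 of these, the lowest being mitosis. The lists had been chosen for being higher, so a high percentile alone says little. A shift in 1 dye or replicate alone is argued against for 5 lists: when lists were chosen as higher in 1 replicate alone, all 13 choices, 6 in replicate 1 and 7 in replicate 2, were higher in the other at p under 0.05 (camera on the values of 1 replicate, preset correlation), and 10 of them were of these 5 lists, the others being of TGF-beta response and hypoxia genes. For 1 list, mitosis, which passed in neither replicate alone, the medians were 0.125 and 0.104 in replicates 1 and 2, but a list chosen by the mean of both would tend to show this, so it stays open there. A response to SP1 loss, an off-target or a transfection response may each give such rises and were not separated.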

How the results depend on the processing

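The alternatives to the comparison as labelled were fixed before the data were examined, except averaging arrays by title; all alternatives by title were added after seeing the data. As labelled, SP1 passed with Agilent's processed signals (-0.56) and the deposited table (-0.56), and ran from -0.74 to 0.32 over leave-outs (0.32 without array 1, -0.74 without array 2, 0.31 without array 3, -0.73 without array 4), because the arrays left then lean to one title. SP1 missed the threshold in the fits to the 4 arrays (limma adjusted p = 0.660 to 0.748). Median centring gave 7827 genes changed, 4708 higher and 3119 lower. Agilent's processed signals put 8423 genes at 2-fold on every array, and the deposited values put 8406 there. At the preset correlation, 8 lists passed camera with Agilent's processed signals and 16 with median centring. No list passed with an estimated correlation (0), and 6 passed in fry, 3 of them among the 11 that passed camera. The cause was not tested. Single genes named as labelled other than SP1 kept direction and call in 3073 of 3083 values, and 10 lost the call. Values with a replicate left out had no test and were counted by direction alone. A gene called in neither setting was counted as keeping its call.

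By title, genes changed, higher and lower were 4313, 2591 and 1722 with Agilent's processed signals, 5405, 3180 and 2225 with offset 0, and 3070, 1877 and 1193 with the deposited table. Genes at 2-fold in both replicates were 329, 162 and 325, and 107 to 121 with either replicate left out, where only 1 value must pass. Without the replicate block 9 genes changed, 5 higher and 4 lower, and SP1 stood at -2.10 (adjusted p = 0.0557), since any difference between the replicates then enters the spread. Lists passing were 0 with an estimated correlation and 0 in fry, both with 1 residual degree of freedom. CDX2 turned to -0.17 in single channels. Of 2276 values of single genes other than SP1, 1998 kept direction and call, 275 lost the call and 2 gained it. The counting was as above, so values with a replicate left out entered by direction alone, without a test. Elsewhere the cause was not tested. The random-block model as labelled gave no list test, which camera does not allow. Between 72.4% and 77.1% of spots were well above background in the RNA labelled control siRNA. Genes that missed this on an array of each title were not tested by title. As labelled, such genes were tested only where the other RNA was well above background on all arrays.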

Other observations

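The test of immediate early genes below was chosen after EGR1, JUN and other genes of their kind had been seen to fall.

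By title, regulators of apoptosis and p53 targets went both ways. Of 29 apoptosis regulators, 11 rose and 9 fell (camera adjusted p = 0.790): BIK rose 1.59-fold and CASP9, an initiator caspase, 0.59 on the log2 scale, while BID fell 1.63-fold. Of 29 p53 targets, 6 rose and 10 fell (adjusted p = 0.103): GDF15, a secreted stress factor, fell 1.70-fold and FDXR 1.58-fold, while RRM2B rose 1.48-fold. Of 25 integrin and basement membrane genes, 9 rose and 6 fell (adjusted p = 0.914), with ITGA3 1.51-fold and ITGA6 1.43-fold lower and ITGB8 1.41-fold higher. MMP9, a matrix protease, was 1.75-fold higher and SERPINB5, a serpin, 1.59-fold lower (list adjusted p = 0.790). AXL, a receptor tyrosine kinase, fell 1.62-fold in a mesenchymal list in which 1 of 21 rose and 5 fell (adjusted p = 0.103).

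Genes induced early after growth stimulation were mostly lower on arrays titled SP1. Beside EGR1 and JUN, FOS fell 1.79-fold (log2 -0.84 ± 0.03, SD, n = 2), IER2 1.79-fold, TRIB1 1.58-fold, DUSP6, a phosphatase of ERK kinases, 1.55-fold and SGK1 1.51-fold. PHLDA1 went the other way and rose 1.84-fold. A hypothesis is that immediate early genes fell as a group. Of 18 such genes outside the named genes and the fixed lists, and without 3 more whose fall had been seen, 12 fell and 2 rose, with a median of -0.27 (camera p = 0.000418; p = 0.163 with an estimated correlation). The group fall is called at the preset correlation only. With an estimated one camera had 1 degree of freedom, so the missed threshold cannot decide whether correlation between genes accounts for it. The members named here were chosen after their values were seen.

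All 4 members of the ID family, inhibitors of helix-loop-helix transcription factors, rose on arrays titled SP1, in each scaling alternative too: ID2 3.27-fold, ID4 2.63-fold, ID1 2.14-fold and ID3 1.64-fold. This grouping was chosen after the values were seen, and the family was not tested as a group. The scaling alternatives use the same 4 arrays and add no independent evidence.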
